A study of Saccharomyces cerevisiae BY4741 with 24 samples.

How the data were processed

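The samples were 24 libraries of polyadenylated RNA from log-phase Saccharomyces cerevisiae BY4741. Per the labels' protocols, cells were grown in rich glucose medium, rapamycin was added to 1 µg/mL and samples were taken at 0, 20, 40, 60, 90 and 120 min. Per the labels, both strains carried the anchor-away background, in which rapamycin joins a protein tagged with FKBP12 on a ribosomal protein (RPL13) to a target and carries it out of the nucleus. The series' design text names RNA polymerase II (RNAPII) as the target, but the genotype labels list no tag on an RNAPII subunit. One strain was labelled wild-type and the other as deleted for SPP1, which encodes a subunit of the Set1 complex (COMPASS), the methyltransferase of histone H3 lysine 4. The strain field of the deletion samples names a different background, with tagged RPB3, while their genotype field gives the anchor-away background; the group was taken from the titles. Per the labels' protocols, 25% S. pombe cells were added before RNA purification, and 500 ng of RNA went into a Lexogen 3′ end library.

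The authors deposited 1 table of signal per gene for the series, made with Bowtie2, SAMtools and bedtools on the genomes sacCer3 and ASM294v2, per the submitters' processing notes. Tool versions, the counting rule, the use of strand, the treatment of reads that map to several places and the formula of the scaling were not given in the sources used here. Reads of overlapping, antisense and near-identical genes can therefore not be told apart. In each library 100% of the values were whole multiples of 1 factor, within 0.01, so the table held read counts multiplied by 1 scale factor per library. These factors ran from 0.470 to 1.913. Whether they come from the S. pombe reads is not recorded in the labels, and every statement about loss of total RNA rests on them.

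The table had 5219 lines with a gene identifier, of which 4 had no values, and 5215 genes were used. Of these, 5113 matched the R64 annotation, from which symbols and coordinates were taken, and 102 did not. Recovered reads ran from 340518 to 992104 per library, with a median of 581493, and the median gene had between 5 and 30 reads. Replicates of a group differed by 7.77 to 22.25 times the counting noise (chi-square per degree of freedom), so no pair looked like repeated deposits of 1 library. The labels call the replicates repeats and do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

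The values were not raw counts, so the tests were run with limma 3.58.1 in R 4.3.3 on log2(value + 2), with the trend option and Benjamini-Hochberg adjustment at 0.05. The pseudocount of 2 is the median over libraries of the 10th percentile of values above 0, to 1 digit. Genes with a mean below the 25th percentile (5.73) of the 5109 genes with a value above 0 in any library were left out, which kept 3832 genes and left out 1383. Fold changes and slopes are on the log2(value + 2) scale and understate the change of low genes. The level comparisons used 1 mean for each of 12 groups of 2 libraries (12 residual degrees of freedom). The decay comparisons used a straight line over time for each strain (20 residual degrees of freedom). They treat the libraries of a time series as independent, so the intervals of slopes and half-lives can be too narrow. A half-life is 1 divided by the rate of loss in log2 units. The design table had assumed normalised values or raw counts, and its branch for normalised values was followed.

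Gene lists were tested with limma camera, with the preset correlation of 0.01 and again with an estimated correlation. Of 22 lists, 18 had at least 5 members past the filter: cytosolic ribosomal proteins, ribosome biogenesis, glycolysis, heat shock, general stress response, Set1 complex, histones, mRNA decay machinery, RNAPII subunits, mitochondrial ribosome, respiratory chain, proteasome, cyclins, pheromone pathway, phosphate regulon, amino acid biosynthesis (Gcn4 targets), ergosterol synthesis, and loci deleted or tagged in the strains. The lists of alpha-specific, meiosis and galactose genes had 1 member each past the filter, and no gene of the mitochondrial genome was analysed here. A further 2 lists, of nitrogen catabolite repressed genes and of phospholipid synthesis, were added after some of their members had been seen. The list tests on each strain's slope used values centred on the library median.

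The groups, tests, filter, lists, most of the other settings tried and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and falls among genes past the threshold for which both deletion-labelled libraries or series lay on the same side of both wild-type ones. Where fewer than 5 genes passed, it also took the 10 with the smallest p. For decay it took the 10 fastest-lost and the 10 slowest-lost genes in each strain among the 1916 at or above the median level at 0 min. It added SPP1, FPR1, MFA2, PGK1, the Set1 complex and 2 to 4 members of each list. Genes with a positive slope, genes that passed at a single time, and genes of the comparison averaged over times were chosen after their values were seen.

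The settings fixed in this way were other pseudocounts, filters, scalings, time windows and treatments of time, the repeat number as a block, leaving out each replicate or time, and DESeq2 1.42.0. For the slopes this block was a separate level for each time series. Added after the data were seen were edgeR 4.0.16 quasi-likelihood tests on the recovered reads, leaving out single libraries, and a strain comparison averaged over all times. The tests were tried on simulated data with 200 of 3832 genes changed. For the comparison at 0 min, 0% of changes of 0.5, 3.50% of changes of 1, 79.5% of changes of 2 and 95.5% of changes of 3 log2 units were recovered. For the slope difference, 0% of differences of 0.5, 15.5% of differences of 1, 86.5% of differences of 2 and 98.5% of differences of 3 log2 units per h were recovered. False calls numbered 0, 1, 7 and 11 at 0 min and 0, 0, 1 and 2 for the slope difference, in the same order of sizes. The simulated libraries were independent draws with no structure by series. With fewer than 200 changed genes the adjusted cutoff is stricter, so these shares can overstate recovery in the real data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.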

Results

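Polyadenylated RNA was measured by 3′ end sequencing in 2 strains of budding yeast at 6 times after rapamycin (0, 20, 40, 60, 90 and 120 min), with 2 repeats per strain and time. The 24 libraries form 12 groups of 2 and 4 time series. In the anchor-away system rapamycin tethers a tagged nuclear protein to ribosomal protein and carries it out of the nucleus, so that, by design, RNA made before the addition decays without replacement. The series' design asks whether transcripts are degraded at a different rate with and without SPP1. Library depth ran from 340518 to 992104 reads, and the median gene had 5 to 30 reads, so single genes of ordinary level were measured with wide error. Values are the authors' scaled read counts, called signal here, and means are given ± SD over n = 2 libraries.

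SPP1 (YPL138C, chromosome XVI, 291366 to 292427, minus strand) encodes a Set1 complex subunit with a PHD finger, and its signal was present in every library, including those labelled as deleted for it. In the wild-type, SPP1 signal in repeats 1 and 2 was 25.3 and 29.3 at 0 min, 14.5 and 17.3 at 20 min, 4.82 and 16.1 at 40 min, 7.08 and 7.92 at 60 min, 4.43 and 4.91 at 90 min, and 3.83 and 2.27 at 120 min. In the libraries labelled spp1Δ it was 16.8 and 8.60 at 0 min, 7.65 and 5.89 at 20 min, 9.43 and 13.1 at 40 min, 17.6 and 10.8 at 60 min, 24.1 and 19.8 at 90 min, and 26.4 and 13.2 at 120 min. These values rest on 4 to 47 reads per library. The labels do not say which part of SPP1 was replaced by the KanMX marker, and 3′ tags from outside the deleted part check nothing, so these samples are called the libraries labelled spp1Δ throughout. FPR1 (YNL135C, chromosome XIV, 371882 to 372226), the FKBP12 prolyl isomerase through which rapamycin inhibits TOR, is labelled as deleted in both strains. Its signal was 52.1 ± 3.64 in the wild-type and 44.0 ± 3.17 in the libraries labelled spp1Δ at 0 min, and the same limit on 3′ tags holds for it.

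**Figure D1:**
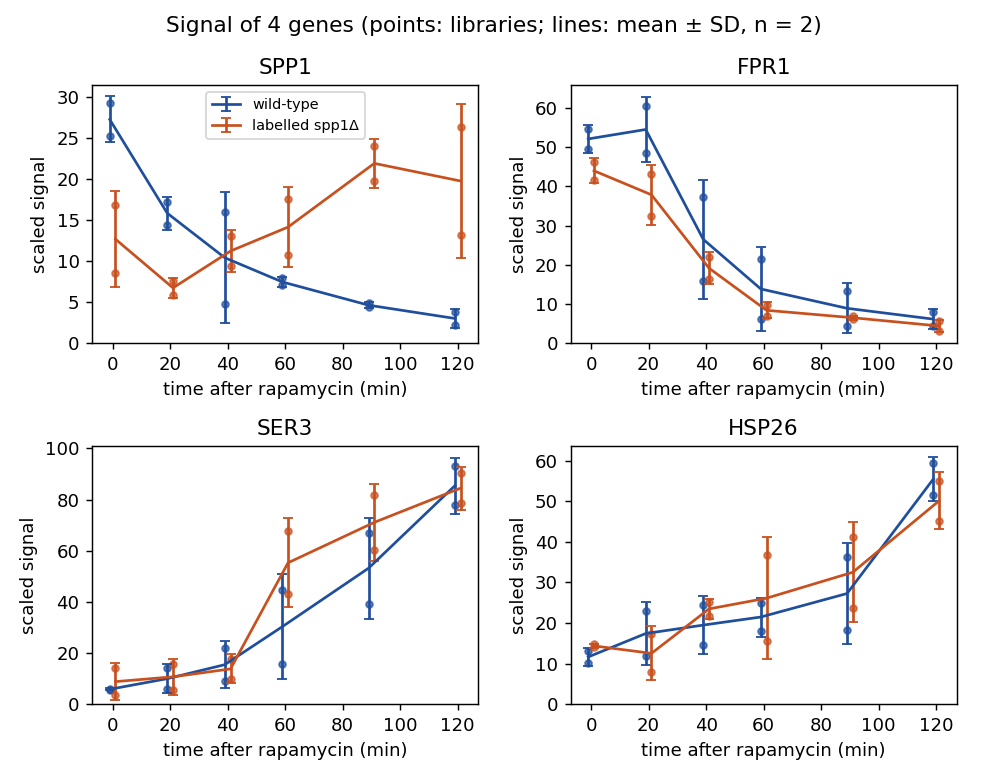
Signal (authors' scaled reads, linear axes from 0) of SPP1, FPR1, SER3 and HSP26 against minutes after rapamycin, with 1 point per library and lines through the means, with SD bars (n = 2), of each strain. SPP1 fell from 27.3 to 3.05 in the wild-type means and lay at 12.7 and 19.8 at 0 and 120 min in the libraries labelled spp1Δ.

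Before rapamycin, the a-factor barrier gene AFB1, the cyclophilin gene CPR2 and the translation initiation factor gene FUN12 had the lower values in the libraries labelled spp1Δ, but no gene passed the test. AFB1 (YLR040C, chromosome XII, 228908 to 229582) had 36.7 ± 1.02 signal in the wild-type and 7.71 ± 2.98 in the libraries labelled spp1Δ, a log2 difference of -2.03 (SE 0.56). CPR2 had 142 ± 24.8 and 65.6 ± 4.27, a difference of -1.09 (SE 0.36), and FUN12, which encodes eIF5B, had 1064 ± 411 and 493 ± 41.1, a difference of -1.05 (SE 0.36). The a-factor genes MFA1 (2015 ± 240 and 1408 ± 0.194, -0.51) and MFA2 (2233 ± 420 and 1409 ± 193, -0.66) and the mating adhesin gene FIG2 (48.4 ± 1.65 and 25.3 ± 5.98, -0.91) had values of the same sign. By limma with Benjamini-Hochberg adjustment, 0 of 3832 genes passed at 0 min, with 98 at an unadjusted p under 0.05. Other tools also gave 0, with 99 such genes by edgeR with the authors' scaling, 113 by edgeR with TMM and 67 by DESeq2. Each of these counts lies below a share of 0.05 of the 3832 genes, which uniform p-values would give without any change. The counts are therefore no sign of change, and the absence of calls does not show that the strains are equal. The smallest unadjusted p-values in limma were 9.2e-04 for AFB1, 0.0030 for DFG10, 0.0035 for the mitochondrial helicase gene MRH4, 0.0046 for CPR2, 0.0049 for the splicing factor gene CEF1, 0.0056 for CBP3, 0.0062 for FUN12, 0.0073 for the Rab GTPase gene YPT32 and 0.0076 for SPR6. Without wild-type repeat 1 at 0 min, the differences were -3.61 for CEF1 and -2.60 for the squalene synthase gene ERG9 (named after its value was seen). Both then rest on wild-type repeat 2 alone, which had 100 reads of CEF1 against 11 in repeat 1, and 563 reads of ERG9 against 107. The libraries labelled spp1Δ had 3 and 10 reads of CEF1 and 62 and 99 of ERG9. With a pseudocount 10 times larger, AFB1 passed (-1.04).

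The other genes named in advance also did not pass at 0 min. SPP1 itself differed by -1.05 (SE 0.49) and the glycolytic gene PGK1, with 1489 ± 535 and 1843 ± 541 signal, by 0.32 (SE 0.34). Of the Set1 complex, the catalytic subunit gene SET1 differed by -0.44 (SE 0.44), BRE2 by 0.92 (SE 0.55), SWD3 by 0.32 (SE 0.51) and SDC1 by -0.11 (SE 0.54). Over all genes the median difference was -0.23 with a median SE of 0.48, so list tests, which set a list against the other genes, can point up where a list's median is negative. None of the 18 lists passed limma camera with the preset correlation. The MATa and pheromone list came closest, with a median of -0.51 (Benjamini-Hochberg adjusted p = 0.077 in limma camera, adjusted p = 0.986 with an estimated correlation), and 1 of its 13 members, AFB1, fell when adjusted over the list alone. In the other 17 lists 0 members passed over all genes or adjusted over the list alone, and the medians lay between -0.11 and -0.30. The single measured members of the alpha-specific, meiosis and galactose lists had differences of -0.34, -0.29 and -0.53.

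In the wild-type, most transcripts fell after rapamycin, with AAH1, AIM29, GPP1 and PMA1 fastest among the better-expressed genes, while 11 genes, SER3, GAP1, ZPS1 and HSP26 among them, rose. AAH1 (YNL141W, adenine deaminase) fell from 300.3 ± 36.3 to 7.27 ± 1.45 signal between 0 and 120 min, a slope of -2.59 log2 units per h (SE 0.17) and a half-life of 23.2 min (95% interval 20.5 to 26.7). PMA1, the plasma membrane proton pump, fell from 641 ± 164 to 19.7 ± 10.7 (half-life 24.7 min) and the enolase gene ENO1 from 356 ± 39.5 to 21.98 ± 23.1 (26.3 min). The opposite was seen for SER3 (YER081W), which encodes 3-phosphoglycerate dehydrogenase of serine synthesis and rose from 5.85 ± 0.316 to 85.4 ± 10.9, a slope of 1.80 (SE 0.23). The small heat shock protein gene HSP26 rose from 11.6 ± 2.14 to 55.5 ± 5.46, a slope of 0.91 (SE 0.20). The total signal of the wild-type libraries was 1004418 and 1002385 at 0 min and 79.4 ± 0.966%, 54.0 ± 8.66%, 50.1 ± 8.27%, 31.7 ± 1.11% and 25.7 ± 3.40% of the own 0 min value at 20, 40, 60, 90 and 120 min (n = 2). By limma with Benjamini-Hochberg adjustment, 3652 of 3832 genes fell and 11 rose over time. The median slope was -1.15 per h (median SE 0.22), and the half-lives of 3802 genes with a negative slope had a median of 52.1 min and quartiles of 42.7 and 67.8 min. On the log2(value + 2) scale the median gene fell less after 60 min, standing at -1.58 log2 units from 0 min at 60 min and at -2.18 at 120 min. In the libraries labelled spp1Δ these values were -1.40 and -2.08. Total signal showed no such slowing, with 50.1% at 60 min and 25.7% at 120 min in the wild-type. The pseudocount flattens the fall of low genes, and whether loss itself slowed was not tested. All half-lives given are those of a straight line over 0 to 120 min. They depend on that window and, for genes with few reads, on the pseudocount.

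**Figure D2:**
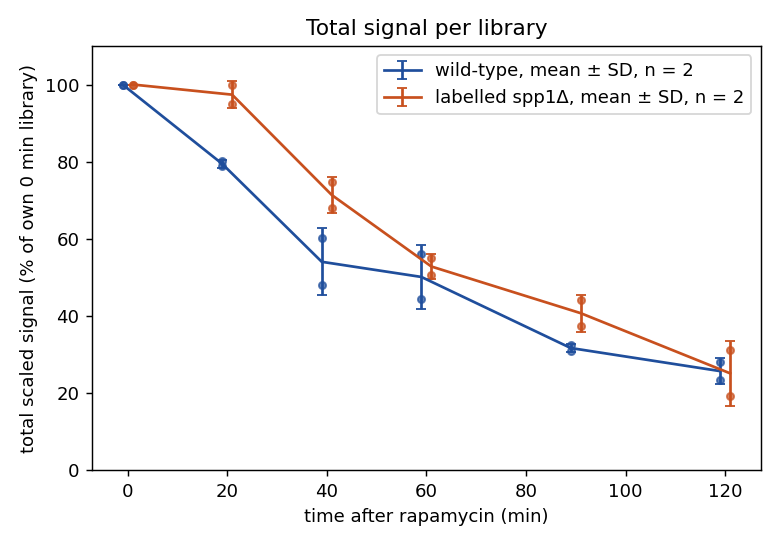
Total scaled signal of each library as a percentage of its own 0 min library (linear axis) against minutes after rapamycin, with 1 point per library and lines through the means with SD bars (n = 2). At 20 min the wild-type libraries lie at 78.8 and 80.1% and those labelled spp1Δ at 99.9 and 94.8%; at 120 min the means are 25.7 and 25.1%.

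The other 7 of the 10 fastest-lost wild-type transcripts had half-lives of 24.3 to 26.2 min. They were AIM29 (-2.47 per h), the glycerol phosphatase gene GPP1 (-2.45), RCF2 of the respiratory supercomplexes (-2.39), the methionine salvage gene MDE1 (-2.36), ATO3 (-2.35), the tRNA methyltransferase gene ABP140 (-2.34) and MRH1 (-2.29). At the slow end, transcripts of CDC53, the cullin of SCF ubiquitin ligases, had a slope of 0.59, the RNA-binding protein gene MRN1 0.45, the argininosuccinate lyase gene ARG4 0.44 and ASI3 0.40, and all 4 passed as rises. The polyubiquitin gene UBI4 (0.42), NGR1 (0.13), the glutamate dehydrogenase gene GDH1 (0.08), POB3 of the FACT complex (0.06), CLG1 (-0.003) and the nicotinamidase gene PNC1 (-0.01) did not pass in either direction. Outside the named rule, the amino acid permease gene GAP1 (1.79), the zinc-responsive gene ZPS1 (1.12), the Hsp70 gene SSA4 (0.70) and the glycogen debranching gene GDB1 (0.47) also rose. Without wild-type repeat 1 the slopes of CDC53 (0.10), MRN1 (-0.07), GDB1 (0.11), SSA4 (0.46), ARG4 (0.38) and ASI3 (0.40) no longer passed, of which those of ARG4 and ASI3 changed little in size. ASI3 (0.41) also did not pass without repeat 2, nor without the 20, 40, 90 or 120 min libraries (0.39, 0.32, 0.37 and 0.32). MRN1 (0.38) and GDB1 (0.41) did not pass without the 0 min libraries. With 0 to 60 min alone HSP26 (0.75), CDC53 (0.59), GDB1 (0.51), SSA4 (0.16), ARG4 (0.12) and ASI3 (-0.06) did not pass, nor with time as a factor CDC53 (0.56), MRN1 (0.42), SSA4 (0.36), ARG4 (0.28) and ASI3 (0.22).

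Each direction depends on the authors' scaling, because other scalings set the median library change to about 0. With libraries centred on their median, 336 wild-type transcripts fell and 578 rose, relative to a median of -1.15 per h. Upper-quartile scaling gave 819 down and 387 up, DESeq2 618 down and 611 up, and edgeR with TMM 589 down and 589 up, against 3677 in all by edgeR with the authors' scaling. Against 0 min, by limma with Benjamini-Hochberg adjustment, 0 wild-type genes passed at 20 min (294 at an unadjusted p under 0.05), 2101 at 40 min, 3092 at 60 min (3 up), 3548 at 90 min (4 up) and 3552 at 120 min (7 up). The median gene stood at -0.36, -1.14, -1.58, -2.01 and -2.18 log2 units at these times. On centred values the counts were 0 (131 at an unadjusted p under 0.05), 14, 313, 424 and 569.

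Among the lists, transcripts of the proteasome, of stress and heat shock genes and of the respiratory chain had higher slopes over 0 to 120 min than other wild-type transcripts. In wild-type repeats 1 and 2 the median change from 0 min of all genes was -1.61 and -1.53 at 60 min, and -2.05 and -2.30 at 120 min. The respiratory chain stood at -1.39 and -1.53, then -1.13 and -1.79, and the proteasome at -1.03 and -0.78, then -1.19 and -1.24. Whether loss was slower or signal was gained late was not tested. Proteasome transcripts fell for 28 of 33 members, for example PRE1 (half-life 58.9 min) and RPT1 (59.8 min), and the half-life of the list's median slope was 94.6 min. Respiratory chain transcripts fell for 29 of 33, such as ATP15 (42.9 min) and COX5A (55.8 min), with 82.0 min at the median. Heat shock transcripts fell for 19 of 26, such as YDJ1 (50.7 min) and KAR2 (56.3 min), and 2, HSP26 and SSA4, rose. General stress transcripts fell for 9 of 18, such as the thioredoxin gene TRX2 (79.2 min) and YGP1 (45.3 min). Relative to the library median, 26 of 33 proteasome, 12 of 18 stress, 13 of 26 heat shock and 18 of 33 respiratory transcripts had higher slopes over all genes, and 28, 14, 16 and 19 adjusted over the list alone. The median centred slopes were 0.55, 0.69, 0.46 and 0.46 per h. Their adjusted p-values in limma camera (Benjamini-Hochberg, preset correlation) were 1.2e-11, 9.9e-07, 2.7e-08 and 1.7e-06, and these calls held with an estimated correlation, with adjusted p = 0.012, 0.021, 0.021 and 0.027. On the values as deposited no list passed with an estimated correlation, and of the named members TRX2 (0.43) passed as a rise with centred values, while PRE1 (0.17), RPT1 (0.18), KAR2 (0.12), COX5A (0.11), YDJ1 (0.004), YGP1 (-0.14) and ATP15 (-0.21) passed in neither direction.

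Ribosome biogenesis and glycolysis transcripts had medians below the wild-type median slope. Of ribosome biogenesis transcripts 108 of 109 fell, such as NOP58 (28.3 min) and the nucleolin gene NSR1 (36.4 min), and all 18 glycolysis transcripts fell, such as ADH1 (33.1 min) and PGK1 (36.5 min). Their median centred slopes were -0.12 (adjusted p = 0.0036 in limma camera, Benjamini-Hochberg) and -0.24 (adjusted p = 0.014), and neither held (adjusted p = 0.335 and 0.446 with an estimated correlation). Transcripts of amino acid biosynthesis fell for 36 of 43, such as LEU9 (39.2 min) and ILV5 (34.3 min), while 2, SER3 and ARG4, rose. That list's median centred slope was 0.30 (adjusted p = 8.9e-05 in limma camera, Benjamini-Hochberg; adjusted p = 0.335 with an estimated correlation). The other lists did not pass on centred values. As deposited, cytosolic ribosomal proteins and ergosterol synthesis passed as down with the preset correlation only (Benjamini-Hochberg adjusted p = 2.8e-08 and 0.0033 in limma camera, adjusted p = 0.665 for each with an estimated correlation). limma camera compares slopes divided by their error, so this direction need not be that of the slopes. The median slope was -1.24 per h for ergosterol synthesis and -1.05 for ribosomal proteins, the latter above the -1.15 of all genes. Falls were counted for 135 of 136 cytosolic ribosomal protein transcripts (RPS26B 35.0 min, RPL16A 38.0 min), 58 of 60 of the mitochondrial ribosome (MRP2 32.1 min, MRPL37 35.6 min) and 56 of 59 of mRNA decay (PAB1 31.6 min, MTR4 33.8 min). They were also counted for 20 of 21 of ergosterol synthesis (ERG1 28.2 min, ERG11 35.7 min), 10 of 10 histone (HTZ1 37.7 min, HHO1 34.7 min), 10 of 10 RNAPII (RPB7 37.6 min) and 12 of 12 cyclin (CDC5 33.4 min, CLB1 31.6 min) transcripts. The same held for 11 of 13 pheromone (STE4 37.1 min, MFA2 49.5 min), 8 of 8 phosphate (VTC2 47.7 min, SPL2 44.2 min) and 6 of 6 deleted or tagged (FPR1 38.2 min, SPP1 49.1 min) genes. All 5 Set1 complex transcripts fell, with half-lives of 35.8 min for SET1, 43.4 min for BRE2, 48.0 min for SWD3 and 48.5 min for SDC1. BRE2 had 10 and 9 reads at 0 min and 1 and 0 at 120 min. The pseudocount of 2 limits how fast such a fall can appear, so its half-life is not a measured rate of decay. The count of falls adjusted over the list alone was 28 for the respiratory chain and 18 for heat shock, and equal to the count over all genes in the remaining 16. The single measured alpha-specific, meiosis and galactose genes had slopes of -0.81, -0.998 and -0.71.

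**Figure D3:**
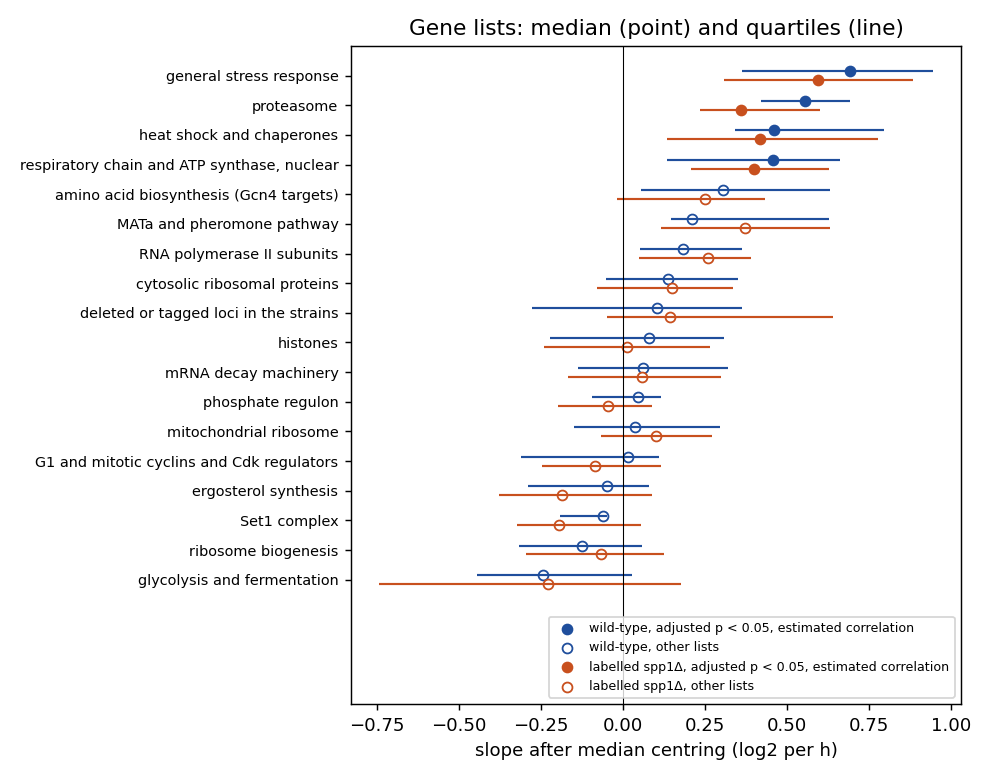
Median (point) and quartiles (line) of the slope of each gene list, on values centred on the library median, in log2 units per h for the wild-type and the libraries labelled spp1Δ; 0 is a transcript lost at the library's median rate. Filled points mark the 4 lists at the top, with medians of 0.46 to 0.69 in the wild-type and 0.36 to 0.59 in the other strain, that passed limma camera with an estimated correlation.

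In the libraries labelled spp1Δ the loss ran over the same range of rates. MDE1 fell from 146 ± 27.5 to 4.56 ± 4.86 signal (-2.69 per h, SE 0.21, half-life 22.3 min) and the RNA helicase gene DBP2 from 1835 ± 883 to 71.0 ± 70.5 (-2.53, SE 0.22, 23.8 min). AAH1 fell with a half-life of 24.2 min and PMA1 with 24.6 min, followed by SWM1 (24.6 min), MRH1 (25.5 min), HEK2 (25.7 min), the fatty acid synthase gene FAS1 (25.9 min) and ATO3 (25.9 min). SER3 rose from 8.85 ± 7.30 to 84.5 ± 8.42 (1.82 per h, SE 0.23) and HSP26 from 14.4 ± 0.512 to 50.1 ± 7.01 (0.88, SE 0.20). GAP1 (1.08), ZPS1 (0.73), GDB1 (0.70), the autophagy gene ATG8 (0.64) and ARG4 (0.32) also rose, whereas MRN1 (0.36), CDC53 (0.20), the citrate synthase gene CIT1 (0.04), ASI3 (0.04), PNC1 (0.03), UBI4 (0.02), GDH1 (0.005) and the TFIIH helicase gene SSL2 (-0.06) passed in neither direction. In all, 15 genes rose in either strain and 6 in both, SER3, GAP1, ZPS1, HSP26, GDB1 and ARG4. The rises of ATG8 (-0.13), ARG4 (0.22) and GDB1 (0.33) did not pass without repeat 1 labelled spp1Δ, nor those of GAP1 (0.55) and ARG4 (0.43) without repeat 2 labelled spp1Δ. ARG4 and ATG8 did not pass without the 0 min libraries (0.26 and 0.58) or the 90 min libraries (0.25 and 0.55), ARG4 without the 20 min libraries (0.34) or without wild-type repeat 2 (0.32), and GAP1 without the 120 min libraries (0.98) or by edgeR with the authors' scaling (0.71). With 0 to 60 min alone ZPS1 (1.10), HSP26 (0.87), ATG8 (0.62), ARG4 (0.32) and GAP1 (-0.17) did not pass, nor with time as a factor ATG8 (0.60) and ARG4 (0.29).

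By limma with Benjamini-Hochberg adjustment, 3647 genes fell and 10 rose in the libraries labelled spp1Δ, with a median slope of -1.13 per h and a median half-life of 53.1 min over 3804 genes (quartiles 43.0 and 69.1 min). Centring gave 347 down and 476 up, upper-quartile scaling 701 and 391, DESeq2 571 and 520, and edgeR with TMM 547 and 490. The total signal was 901163 and 904504 at 0 min and 97.4 ± 3.57%, 71.4 ± 4.78%, 52.8 ± 3.20%, 40.7 ± 4.84% and 25.1 ± 8.42% of the own 0 min value at the later times (n = 2). Relative to the library median, 13 of 33 proteasome, 12 of 18 stress, 12 of 26 heat shock and 17 of 33 respiratory transcripts had higher slopes over all genes, and 18, 12, 14 and 19 adjusted over the list alone. The median centred slopes were 0.36, 0.59, 0.42 and 0.40 per h, with adjusted p-values in limma camera (Benjamini-Hochberg, preset correlation) of 9.1e-07, 3.3e-06, 9.1e-07 and 8.2e-07, and with adjusted p = 0.034 for each with an estimated correlation. Ribosome biogenesis (-0.07), glycolysis (-0.23), Gcn4 targets (0.25) and the pheromone list (0.37) passed in limma camera with the preset correlation only. Their Benjamini-Hochberg adjusted p-values were 0.024, 0.0052, 0.0056 and 0.024, against adjusted p = 0.409, 0.323, 0.466 and 0.323 with an estimated correlation. As deposited, cytosolic ribosomal proteins (4.4e-07) and ergosterol synthesis (0.0048) passed as down and the mitochondrial ribosome (0.036) as up in limma camera, also with the preset correlation only. Their median slopes were -1.01, -1.35 and -1.06 per h against -1.13 for all genes, so that of the ribosomal proteins was not lower. Half-lives of always-named genes were 57.5 min for MFA2, 31.1 min for PGK1, 38.8 min for FPR1, 40.0 min for SET1, 44.3 min for BRE2, 40.4 min for SWD3 and 54.3 min for SDC1. BRE2 had 17 and 15 reads at 0 min and 1 and 5 at 120 min, so the pseudocount limits its half-life here too.

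SPP1 was the 1 gene that passed the test for a difference in slope between the strains. Its slope was -1.22 per h in the wild-type and 0.54 in the libraries labelled spp1Δ (SE 0.22 each), so its signal fell in one and rose in the other (adjusted p = 0.019 for the rise, by limma with Benjamini-Hochberg adjustment). The rise alone did not pass without repeat 1 (0.47) or 2 (0.60) labelled spp1Δ, without the 20 min (0.39) or 90 min libraries (0.44), with time as a factor (0.28) or with 0 to 60 min alone (0.32). The difference was 1.76 log2 units per h (SE 0.31, 95% interval 1.14 to 2.38, Benjamini-Hochberg adjusted p = 0.0033 in limma). Both series labelled spp1Δ (0.60 and 0.47) lay above both wild-type series (-1.03 and -1.42). In all, 49 genes had an unadjusted p under 0.05, and edgeR with the authors' scaling, edgeR with TMM and DESeq2 also called 1 gene each, with 98, 170 and 168 such genes. Each count again lies below a share of 0.05 of the genes tested. The call was lost without repeat 1 (1.70, adjusted p = 0.285) or 2 (1.82, 0.114) labelled spp1Δ or wild-type repeat 2 (1.57, 1.00), and without the 0 min (1.82, 0.058), 20 min (1.62, 0.076), 90 min (1.66, 0.119) or 120 min libraries (2.06, 0.098), with time as a factor (1.55, 0.313) or 0 to 60 min alone (1.99, 0.999), all by limma with Benjamini-Hochberg adjustment. Grouping the 4 series by repeat number instead of strain gave 6 genes, and with the repeat number as a block of level and slope the strains differed in 1 gene.

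**Figure D4:**
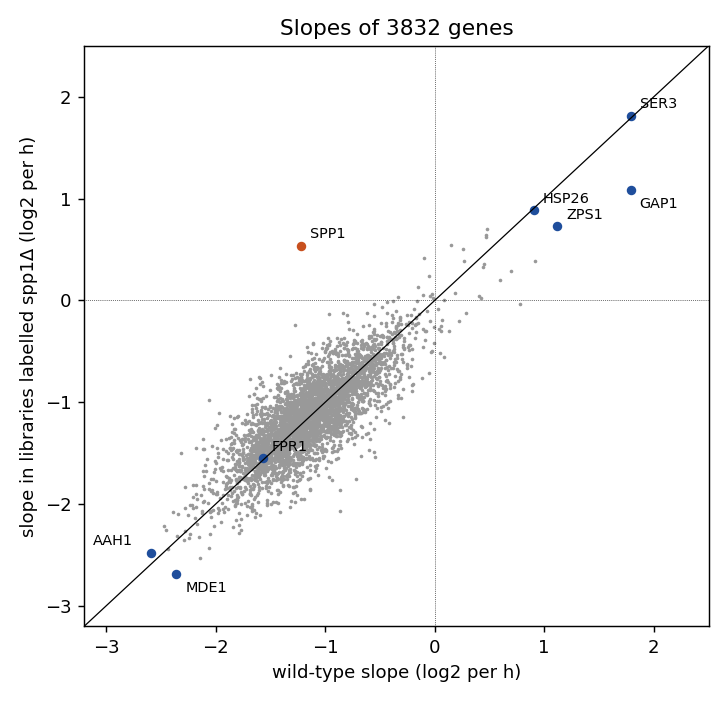
Slope of each of 3832 genes in log2 units per h in the wild-type (x axis) and in the libraries labelled spp1Δ (y axis), from the straight-line model, with the line of equal slopes. SPP1 lies at -1.22 and 0.54, off the line, while SER3, HSP26, ZPS1 and GAP1 are above 0 in both strains.

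No other transcript passed the test for a difference in rate. The next smallest unadjusted p-values in limma were 7.6e-04 for YDR524C-A (-1.21 per h), 0.0049 for the vacuolar carboxypeptidase gene CPS1 (-0.999), 0.0093 for TML25 (0.86), 0.010 for DSC3 (-0.997), 0.011 for PMP2 (-0.66), 0.012 for AFB1 (1.07), 0.013 for the valine and isoleucine synthesis gene ILV3 (-0.73), 0.015 for the elongation factor gene SPT5 (-0.86), 0.016 for the citrate carrier gene CTP1 (0.82) and 0.019 for RRP14 (-0.73). YDR524C-A (-1.97, adjusted p = 0.027 by limma with Benjamini-Hochberg adjustment) passed without the 0 min libraries. The differences were 0.17 for MFA2 (95% interval -0.20 to 0.54), -0.29 for PGK1 (-0.70 to 0.12), 0.17 for SET1 (-0.42 to 0.77), 0.03 for BRE2, -0.23 for SWD3, 0.13 for SDC1 and 0.02 for FPR1 (-0.61 to 0.66). The 95% interval lay within 1 log2 unit per h of 0 for 78.9% of genes, within 1.5 for 99.0% and within 0.5 for 5.74%. These intervals treat the libraries of a series as independent and can be too narrow. Over whole series, the interval for the median slope alone, given next, spanned nearly 1 log2 unit per h to each side. The median slopes of the series were -1.14 ± 0.134 in the wild-type and -1.13 ± 0.285 in the libraries labelled spp1Δ (n = 2), with an exact permutation p of 1 where 0.333 is the smallest possible (two-sided), and the interval of the difference was -0.95 to 0.97. Across genes, which are not independent replicates, the slopes of the strains had Pearson's r = 0.80 and Spearman's rho = 0.77. Between single series rho was 0.55 to 0.67 across the strains, 0.65 between the wild-type repeats and 0.58 between those labelled spp1Δ.

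Of the 18 lists, 4 passed for the slope difference in limma camera with the preset correlation and none with an estimated one. The proteasome list had a median difference of -0.14 per h (Benjamini-Hochberg adjusted p = 0.0107, adjusted p = 0.987 with an estimated correlation), although 0 of its 33 members passed over all genes or adjusted over the list alone. Its leading members were RPN3 (-0.62), RPN6 (-0.40) and RPT6 (-0.30). The Gcn4 targets had a median of -0.05 (adjusted p = 0.0419 in limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.987 with an estimated correlation) and 0 of 43 passing members by either count. The Set1 complex (0.13) and the deleted or tagged loci (0.16) each had an adjusted p of 0.0265 in limma camera with Benjamini-Hochberg adjustment, and adjusted p = 0.657 with an estimated correlation. Both lists contain SPP1, which was the 1 member of each to pass over all genes and adjusted over the list alone. In the other 14 lists 0 members passed by either count and the medians lay between -0.10 and 0.08.

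At single times after rapamycin, ILV3 (YJR016C, chromosome X, 464451 to 466208) and YDR524C-A were the genes with a higher level in the libraries labelled spp1Δ, both at 20 min. ILV3 had 205 ± 126 signal in the wild-type and 844 ± 120 in the libraries labelled spp1Δ (log2 difference 2.18, SE 0.39, adjusted p = 0.0090). YDR524C-A had 134 ± 17.9 and 732 ± 491 (2.25, SE 0.46, adjusted p = 0.043), both by limma with Benjamini-Hochberg adjustment; both were named after their values were seen. On values centred on the library median the differences were 2.13 for ILV3 and 2.21 for YDR524C-A, and 0 genes passed at 20 min (Benjamini-Hochberg adjusted p = 0.093 and 0.108 in limma). At 40, 60, 90 and 120 min limma called 0 genes, with 126, 149, 83 and 116 at an unadjusted p under 0.05, and edgeR and DESeq2 were not run on single later times. Changes from 0 min differed between the strains for 0 genes in limma at each later time, with 61, 100, 136, 94 and 44 genes at an unadjusted p under 0.05. All these counts at single times lie below a share of 0.05 of the genes tested. The total signal at 20 min was 78.8 and 80.1% of the 0 min value in the wild-type libraries and 99.9 and 94.8% in those labelled spp1Δ, a separation with an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow.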

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

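The tests of explanations and the splits of whole series in this part were chosen after the results were seen, and the count over random splits of single libraries was set beforehand. SPP1 differed in slope between the strains by 1.76 log2 units per h, in a test of the difference itself, because its signal fell in the wild-type and rose in the libraries labelled spp1Δ. In 3 of 100 splits of the libraries within each time, the real one included, at least 1 gene passed (real 1, highest of the others 1), which excludes a random grouping of single libraries at 0.05, but these splits break up the 4 time series. Of the 3 splits of whole series, which are too few for a share under 0.05, 2 gave at least 1 gene (real 1, highest of the others 6). The 6 genes came from the split by repeat number, several times the real count, which points to a structure of the samples by repeat. With the repeat number as a block of level and slope, 1 gene passed in the strain comparison.

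With the wild-type labels taken as right, wild-type cells in the libraries labelled spp1Δ would give at most the wild-type's SPP1 signal, but the log2 difference averaged over 90 and 120 min was 1.95 (SE 0.35). Reads running over from the neighbours UME1 or GIP3 would need a neighbour that rises, but the higher of their slopes in these libraries was -1.19 (SE 0.19), for UME1. Both values argue against these as the whole cause of the rise. Strain labels swapped between the groups stay open, since the SPP1 difference at 0 min, -1.05 (SE 0.49), did not pass and 3′ tags from outside the deleted part would not show a swap. A transcript made at the altered locus, for example from the marker, may be the source, as an untested hypothesis, and no biological explanation was tested.

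The remaining results are given as values. The slopes of 4 gene lists differed between the strains with the preset correlation: the Set1 complex (Benjamini-Hochberg adjusted p = 0.0265 in limma camera, adjusted p = 0.657 with an estimated correlation), the proteasome (0.0107 and 0.987), the Gcn4 targets (0.0419 and 0.987) and the deleted or tagged loci (0.0265 and 0.657). POB3 had slopes above 0 in both wild-type series and below 0 in both series labelled spp1Δ, a difference of -0.35 log2 units per h with an unadjusted p of 0.091 in limma and an adjusted p of 1.00 (Benjamini-Hochberg).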

How the results depend on the processing

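Tests by edgeR, single left-out libraries, the adjustment of the added lists over all lists, and the block of level and slope were chosen after the data were seen. At 0 min the count of genes was 0 in 17 of 20 alternatives, 1 with the pseudocount times 10 and 0 to 2 without single replicates. The slope counts stayed within 1.5 times in 20 of 24 alternatives for each strain (3100 to 3671 and 2748 to 3660 without single replicates). They were 914 (wild-type) and 823 (labelled spp1Δ) after centring, 1206 and 1092 with upper-quartile scaling, 1229 and 1091 with DESeq2, and 1178 and 1037 with edgeR and TMM, because these scalings remove the common loss by construction. On centred values 0 genes passed between the strains at 20 min, where the differences of ILV3 (2.13) and YDR524C-A (2.21) stayed near those as deposited, and 14, 313, 424 and 569 wild-type genes differed from 0 min at 40, 60, 90 and 120 min. SPP1 passed for the slope difference in 38 of 48 alternatives (0.73 to 2.16 log2 units per h, adjusted p from 1.1e-06 to 1.00 with Benjamini-Hochberg adjustment in limma, edgeR or DESeq2). These 48 include the 24 fits without a single library, in all of which it passed, so every loss lay among the other alternatives. The fit of 20 to 120 min alone and that without the 0 min libraries are the same fit and are both counted. The count was 0 with the filter at the median, which removes SPP1, with 0 to 60 min alone, with time as a factor, and without the 20, 90 or 120 min libraries, and 0 to 1 without single replicates. Time as a factor keeps all libraries and rests the difference on 0 and 120 min alone, while the other fits named here, except the filter, hold fewer libraries; further causes were not tested. Of the list calls for the slope difference, 0 held with an estimated correlation and 2 after centring. The difference of median slopes stayed between -0.19 and 0.21. Of the named genes' values, those of uncalled genes changed sign in 8 of 296 cases at 0 min, 24 of 1507 and 29 of 763 for the slopes, and 33 of 566 for the slope difference. Depth limits low genes most, since the median gene had 5 to 30 reads. Fits without a replicate leave 1 library per group, which is taken to vary like the others.

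Slopes that lay below 0 as deposited turned above 0 under other scalings, which remove most of the common loss. In the wild-type, after centring, these were CLG1 (1.19), PNC1 (1.18), TRX2 (0.43), RPT1 (0.18), PRE1 (0.17), KAR2 (0.12), COX5A (0.11) and YDJ1 (0.0043). With upper-quartile scaling CLG1 (1.09), PNC1 (1.09), TRX2 (0.36), RPT1 (0.091), PRE1 (0.081), KAR2 (0.051) and COX5A (0.025) did so. With DESeq2 the values were 1.24 for CLG1, 1.29 for PNC1, 0.49 for TRX2, 0.22 for RPT1, 0.22 for PRE1, 0.17 for KAR2, 0.14 for COX5A, 0.059 for YDJ1 and 0.040 for MFA2. With edgeR and TMM they were 1.24 for CLG1, 1.30 for PNC1, 0.49 for TRX2, 0.22 for RPT1, 0.23 for PRE1, 0.18 for KAR2, 0.15 for COX5A, 0.066 for YDJ1 and 0.048 for MFA2. In the libraries labelled spp1Δ, SSL2 and MFA2 turned to 1.10 and 0.12 after centring, 1.07 and 0.13 with upper-quartile scaling, 1.21 and 0.21 with DESeq2, and 1.22 and 0.21 with edgeR and TMM, and SDC1 to 0.055 after centring. In the other direction, MRN1 ran from -0.068 to 0.96 without wild-type replicate 1 or 2, ATG8 from -0.13 to 1.42 without replicate 1 or 2 labelled spp1Δ, and with 0 to 60 min alone ASI3 turned to -0.065 in the wild-type and GAP1 to -0.17 in the libraries labelled spp1Δ, for causes that were not tested.

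The repeat numbers are shared by the strains, but the deviations of same-numbered samples had a correlation above 0 in 5 of 6 times and above 0.1 in 3 (-0.13 to 0.22), which falls short of showing that the numbers pair the samples. The splits by repeat number nonetheless gave more genes than the strains. With the number as a block, 0 genes passed at 0 min (114 at an unadjusted p under 0.05 in limma). With a separate level for each of the 4 time series, 3672 and 3660 genes had a slope and 1 had a slope difference. With the number as a block of level and slope, 1 gene also had a slope difference.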

Other observations

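The tests in this part were chosen after the results were seen, except the count over random splits of single libraries. Averaged over all times, the cyclophilin gene CPR2 (YHR057C, chromosome VIII, 218226 to 218843) was lower in the libraries labelled spp1Δ, with a mean signal of 41.3 against 73.8 over 12 libraries each. The log2 difference was -0.78 (SE 0.14, adjusted p = 0.0061 in limma with Benjamini-Hochberg adjustment), and both libraries labelled spp1Δ lay below both wild-type ones at 6 of 6 times. YNL040W was lower with 16.7 against 43.5 signal (-1.10, SE 0.22, adjusted p = 0.017 in limma with Benjamini-Hochberg adjustment), at 4 of 6 times. After centring on the library median 5 genes passed. The added ones were the phosphatidylcholine synthesis gene OPI3 (0.64, higher at 5 of 6 times), the sphingolipid hydroxylase gene SCS7 (-0.72, lower at 6 of 6) and the lipid droplet gene PLN1 (-0.71, lower at 5 of 6). In 1 of 100 splits within each time, the real one, at least 2 genes passed (highest of the others 1), which excludes a random grouping of single libraries but not of the time series they form. Of the 3 splits of whole series, too few for a share under 0.05, 2 gave at least 2 genes (real 2, highest of the others 43). The 43 genes came from the split by repeat number, many times the real count, which points to a structure of the samples by repeat, and with the repeat number as a block 3 genes differed between the strains. With each series as a random effect 1 gene passed, CPR2, or after centring 4, all of the 5 but PLN1 (adjusted p = 0.189 in limma with Benjamini-Hochberg adjustment), and without single series 0 or 1. In those fits the differences were -0.74 to -0.82 for CPR2 and -0.87 to -1.33 for YNL040W, which was the gene that passed, without repeat 1 labelled spp1Δ. The random-effect fit used 1 correlation shared by all genes and counted its degrees of freedom over libraries. It is therefore not a test of 2 series against 2. As a hypothesis, phospholipid synthesis genes may be raised as a group, but without OPI3, which had been seen, the list gave p = 0.211 in limma camera with an estimated correlation, against 0.0217 with it.

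Nitrogen catabolite repressed genes, which yeast silences while good nitrogen sources last, had a higher median than all genes in the comparison of the strains at 0 min. The list's median was 0.30 over 11 members, against -0.23 for all genes (Benjamini-Hochberg adjusted p = 7.7e-05 in limma camera over the 20 lists tested in all, adjusted p = 0.122 with an estimated correlation and 0.0158 with it on centred values), while 0 members passed over all genes or adjusted over the list alone. Against no change the list did not pass as deposited (limma fry, Benjamini-Hochberg adjusted p = 0.694) and passed on centred values (0.0037), and PUT2 (-0.49) and CAR2 (-0.17) had values below 0 as deposited. Without GAP1 and CPS1, which had been seen before the list was made, the centred median was 0.41 (unadjusted p = 0.0086 in limma camera with an estimated correlation). GAP1 signal at 0 min was 56.1 and 1.23 in the libraries labelled spp1Δ and 4.05 and 0 in the wild-type, so 1 library holds most of it. The added list of phospholipid synthesis had a median of -0.01 at 0 min (adjusted p = 0.485 in limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.981 with an estimated correlation). In the wild-type time course 7 of 11 nitrogen and 10 of 10 phospholipid transcripts fell, by either adjustment, and 1 of the former, GAP1, rose. Their median slope differences between the strains were -0.21 (adjusted p = 0.0305 in limma camera with Benjamini-Hochberg adjustment, adjusted p = 0.987 with an estimated correlation) and 0.09 (0.876 and 0.987), with 0 passing members over all genes or adjusted over the list alone.

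The rise of SER3, GAP1, ZPS1, HSP26, GDB1 and ARG4 in both strains went against the loss of most transcripts. Of these, 0 of the genes other than SER3 overlap another annotated gene, while SER3 overlaps 1, the noncoding SRG1, whose transcription is known to repress it. This argues against reads from within an overlapping annotated range for 5 of them. The ranges were not shown to hold the untranslated ends in which 3′ tags lie, so reads from a neighbour's 3′ end stay open. Nitrogen catabolite repressed genes as a group, which rapamycin induces in sensitive cells, may take part, but without GAP1 and CPS1 their wild-type slope gave p = 0.112 in limma camera with an estimated correlation. Both strains are labelled as deleted for FPR1, through which rapamycin inhibits TOR, and the list of loci deleted or tagged in the strains also holds TOR1. Whether the strains are sensitive to rapamycin was not tested. An error in the scale factors would have to drift by 1.80 log2 units per h for SER3 not to rise (the medians of the wild-type series had an SD of 0.134), which would give the median transcript a half-life of 20.4 min and the fastest named one 13.7 min. These half-lives are possible, so this stays open, as does continued transcription of these genes, for which there was no test.

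The scaled totals of the repeats at 0 min differed by 0.370% in the libraries labelled spp1Δ and 0.203% in the wild-type, against at least 1.52% at later times.

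Total signal at 20 min was a higher share of its 0 min value in the libraries labelled spp1Δ than in the wild-type (exact permutation p = 0.333, the smallest possible). The single library of repeat 1 does not make the pattern, since the other library labelled spp1Δ kept 94.8% of its 0 min total, above the 78.8 and 80.1% of the wild-type libraries. A 0 min scaling that is too low in the libraries labelled spp1Δ could raise all later percentages alike. The ratios of the strains were 1.23, 1.33, 1.06, 1.28 and 0.954 at 20, 40, 60, 90 and 120 min, with p = 0.396 for a difference between times (exact permutation of the libraries within each time, two-sided), which leaves it open. A slower start of the loss in the strain labelled spp1Δ also stays open, as untested.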
